A study of Mus musculus with 16 samples.

How the data were processed

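The series holds 16 Affymetrix MOE430A arrays of total RNA from the bone marrow of mice with 6 leukemias. Each leukemia arose from fetal liver (FL) or bone marrow (BM) cells that were infected with retroviruses carrying Hoxa9 and Meis and then injected into mice. The labels give each leukemia's frequency of leukemic hematopoietic stem cells (L-HSC), which the authors measured by limiting dilution transfer into secondary recipients. The labels state an estimated purity of 95 and an RNA concentration of 0.05 µg/µl for all 16 arrays.

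The values are the deposited intensity signals per probe set, which the authors computed with MAS5 (per the labels; the version is not given). They are linear. The mean of each array, after trimming the lowest and highest 2% of probe sets, lay between 1500.65 and 1500.79, so each array had been scaled to 1 target. Median signals ran from 415 to 580. The deposited run settings per the file headers, of unit "other", hold no expression measurement. They were read only for the scanning session, the chip lot and the fluidics station of each array. Session 1 held every FL array and BMA1 replicate 1, and session 2 held the others. Chip lot 1 covered session 1, BMA1 replicates 2 and 3 and BMA3 replicate 1. Lot 2 covered BMA3 replicate 2 and the BMA5 arrays, and lot 3 was used for BMA3 replicate 3 alone, which also had a run day of its own. BMA3 is thus the only leukemia in more than 1 lot, with 1 array in each, and BMA1 the only leukemia in both sessions. Chip lot as a block therefore rests on single BMA3 arrays, and session as a block rests on BMA1. Station 1 ran FLA2 replicates 1 and 2, BMA1 replicates 2 and 3 and all BMA3 arrays, and station 2 ran the rest.

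Signals were transformed as log2 of the signal plus 16, with no further normalization. Changes are on this scale, which understates those of genes with low signals. Of 22690 probe sets, 64 controls were set aside, and 13809 had a signal above the array median in at least 2 arrays. The platform's table gave 1 gene symbol for 20380 probe sets, several for 691 and none for 1555. Symbols were brought up to date by gene identifier, which matched 20364 of them and left 29 unmatched. Each gene was represented by its probe set with 1 symbol and the highest mean, which left 8529 genes to test of 12394 named on the array. The 1195 probe sets past the filter with several symbols or none were left out of the gene tests.

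Comparisons, gene lists, thresholds and the rule for naming genes were chosen before the data were examined. A linear model with 1 mean per leukemia was fitted in limma 3.58.1 (R 4.3.3) with an empirical Bayes mean-variance trend. The contrasts were FLA2 against the mean of the 4 leukemias of low L-HSC frequency, FLA2 against FLB1, and BMA1 against the mean of BMA3 and BMA5. Origin was tested on the 6 leukemia means, 3 against 3, since origin belongs to the leukemia and not to the array. With a block, these means were first adjusted for it, and the error of that adjustment was not counted in the origin tests. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and a change of at least 2-fold. A gene was specific to a leukemia if it was called in the same direction against each of the 5 others. The position of BMA1 was the median, over the genes called in FLA2 against the low-frequency leukemias, of the BMA1 difference from the low-frequency mean divided by the FLA2 difference. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

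Of 27 gene lists, the 26 with at least 3 measured genes were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a contrast. The same test was run with an estimated correlation, and fry was run as a second test. The lists were retroviral genes (not tested), Hox genes and cofactors, HSC and progenitor genes, polycomb genes, cell cycle genes, cell cycle inhibitors, neutrophil primary and late granule genes, monocyte and macrophage genes, MHC class II genes, B-cell genes, T- and NK-cell genes, erythroid genes, megakaryocyte and platelet genes, mast-cell, basophil and eosinophil genes, marrow stroma and endothelium genes, interferon response genes, Wnt and Notch pathway genes, adhesion and homing genes, immediate early and stress genes, glycolysis genes, hypoxia genes, sex-linked genes, and genes of ribosomal proteins, oxidative phosphorylation and the proteasome.

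Named genes were Hoxa9 and Meis1, plus the called genes with the largest changes whose arrays did not overlap between the groups: up to 12 in each direction for FLA2 against the low-frequency leukemias, and up to 6 in each direction for the other contrasts. For genes specific to a leukemia, up to 3 in each direction were named. In each list, up to 4 called members with the largest change were named, or, if none was called, the 2 with the highest mean. Genes named outside this rule were chosen after their values were seen and are described so.

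The procedure was tested on simulated data with the means and spreads of these arrays and 200 changed genes in each of 5 runs. For the contrasts between leukemias, the spread was that within a leukemia, genes were independent, and unchanged genes had the same mean in every leukemia. The shares called there do not measure how often leukemias differ for other reasons. For FLA2 against the low-frequency leukemias, 85.1% of changes of 1.5 on the log2 scale were called, and 0.0216% of unchanged genes. For origin, 77.6% of changes of that size were called. The real comparisons called 1 to 41 genes, so 200 changed genes loosen the Benjamini-Hochberg cut-off. The shares called can therefore overstate what is detected in the real data. The number of arrays, 2 or 3 per leukemia, limits the precision of every value.

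Alternatives were pseudocounts of 1 and 64, quantile normalization, median centring of each array, no filter, a stricter filter at the 75th percentile, no mean-variance trend, no fold threshold, the mean over all probe sets of a gene, blocks for the replicate number, session, chip lot and fluidics station, leaving out each array or leukemia, only the groups of a contrast, other comparison groups for FLA2, leukemia means, and a random block for the leukemia. Array weights, fits without sex-linked genes, fits within 1 session, lot or station, and the lists with blocks, with median centring, within 1 session or without each array were chosen after seeing the data. The ratios of 3' to 5' probe set signals of Gapdh and actin were compared between groups with 2-sided exact permutation tests on the log2 ratio. The p-values were adjusted over 4 tests, and these tests were also chosen after seeing the data. They treat each array as a separate unit, although the arrays are grouped in leukemias.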

Results

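The data are 16 arrays of total bone marrow cells from mice with 6 leukemias, each started by Hoxa9 and Meis retroviruses in fetal liver (FL) or bone marrow (BM) cells. FLA2, with 3 arrays, has a labelled L-HSC frequency of 1 in 1.4 cells (71.43%). The low-frequency leukemias are FLB1 (2 arrays, 1 in 347 cells, 0.29%), FLB2 (2 arrays, 1 in 72, 1.39%), BMA3 (3 arrays, 1 in 129, 0.78%) and BMA5 (3 arrays, 1 in 183, 0.55%). BMA1, with 3 arrays, has no known frequency. The number of arrays limits the precision. The labels do not say whether the arrays of a leukemia are separate animals, so adjusted p-values measure only the spread between these samples, which may be technical. FLA2 is the only leukemia of high frequency, so the tests compare leukemias and not frequencies.

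Pearson correlations of log2 signals across genes, which are not independent replicates, had a median of 0.942 within a leukemia (0.924 to 0.962, 14 pairs of arrays) and 0.927 between leukemias (0.903 to 0.946, 106 pairs). For 13 of 16 arrays the closest array was of the same leukemia, and the exceptions were both FLB1 arrays and BMA1 replicate 3. Hoxa9, the homeobox gene carried by the retrovirus, had a mean signal of 7109 ± 1170 (SD, n = 3) in FLA2 and single-array signals from 3927 to 9640 over all arrays. Its log2 difference between FLA2 and the low-frequency leukemias was 0.26 (SE 0.15, adjusted p = 0.421). The Meis1 probe set, for the homeobox partner of Hoxa9, had signals from 7.82 to 18.7, below the filter, so it gives no measure of the retroviral Meis transcript.

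The comparison of FLA2 with the low-frequency leukemias asks which genes set apart the leukemia in which most cells act as L-HSC. Igha, the constant region of the IgA heavy chain, fell by 2.98 on the log2 scale (SE 0.30, adjusted p = 6.09e-05), from mean signals of 9306 ± 6714 (SD, n = 2) in FLB1 to 18581 ± 8082 (n = 3) in BMA3 down to 1718 ± 455 (n = 3) in FLA2. Jchain, which joins polymeric IgA and IgM, fell by 2.45 (SE 0.30, adjusted p = 0.000314), and Igkv8-30, a kappa light chain variable gene, fell by 2.01 (SE 0.24, adjusted p = 0.00028). Tfpi, an inhibitor of the coagulation cascade, rose 2.62-fold (SE of log2 0.18, adjusted p = 0.000658). The changes of largest size were at sex-linked genes. Eif2s3y, a Y-linked subunit of a translation initiation factor, rose by 5.30 (SE 0.73, adjusted p = 0.00111; 4.31 with pseudocount 64 and 6.15 with pseudocount 1), and Xist, the RNA that silences an X chromosome in female cells, fell by 4.14 (SE 0.22, adjusted p = 4.73e-09). Eif2s3y signals were 3962 in FLA2 and 2697 in FLB2 but 8.57 in FLB1, 35.4 in BMA1, 49.0 in BMA3 and 13.5 in BMA5, and Xist was low in the same leukemias, FLA2 and FLB2. The signals of Eif2s3y in the other 4 leukemias are far under the array medians, so the size of its change depends on the pseudocount.

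**Figure D1:**
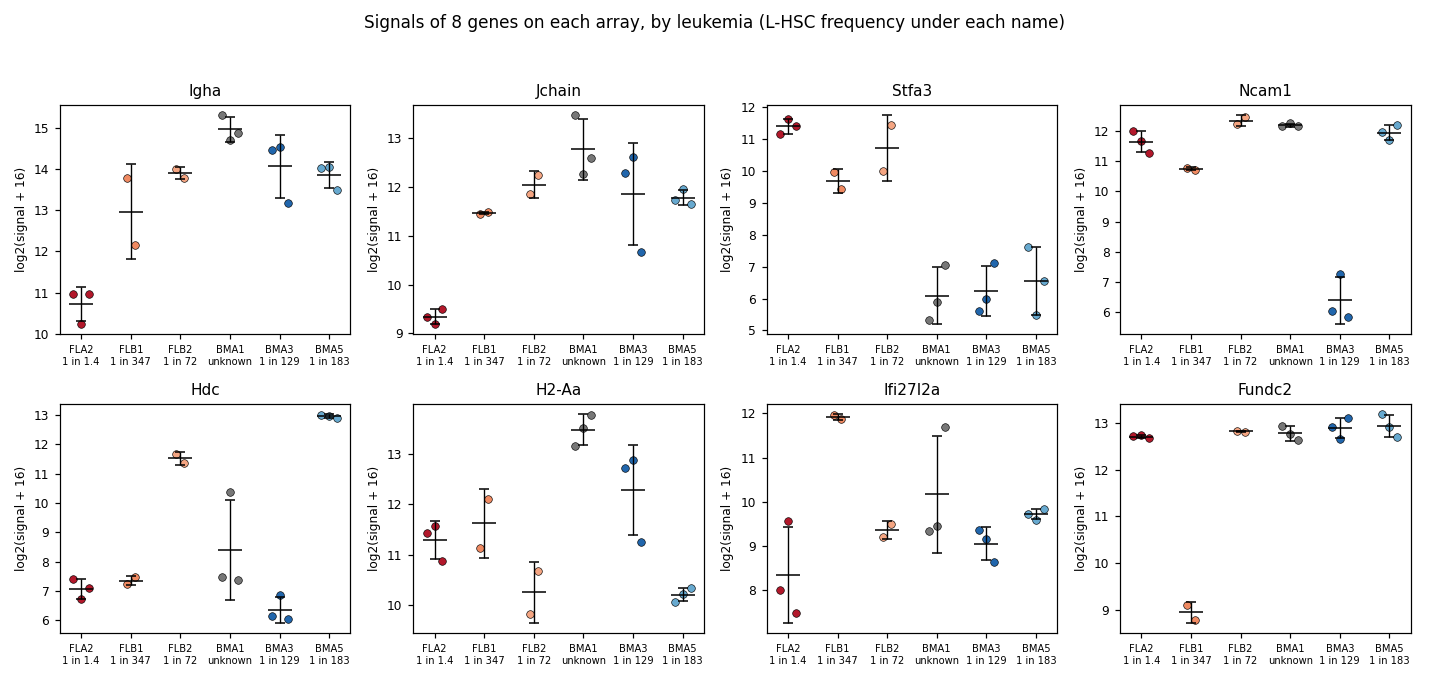
Log2(signal + 16) of 8 genes in each leukemia, with a point per array and a bar with whiskers for the mean and SD. Igha and Jchain are lowest in FLA2, Fundc2 is low only in FLB1, Ncam1 is low only in BMA3, and Stfa3 is higher in the 3 FL leukemias than in the 3 BM leukemias.

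Other genes named by the rule were Ddx4, a germ-cell RNA helicase, which fell by 2.81 (SE 0.32, adjusted p = 0.000185), Atp6v1a, a subunit of the vacuolar proton pump, which fell by 1.16 (SE 0.15, adjusted p = 0.000658), Nudt9, an ADP-ribose pyrophosphatase, which fell by 1.13 (SE 0.18, adjusted p = 0.00608), and Tmppe, which fell by 1.44 (SE 0.28, adjusted p = 0.0211). Smaller rises were at Lcorl (log2 1.28, SE 0.28, adjusted p = 0.0441), Clec11a, a secreted growth factor of the lectin family (log2 1.06, SE 0.21, adjusted p = 0.0254), and Zmynd11, a chromatin reader (log2 1.04, SE 0.20, adjusted p = 0.0223). Among list members, Hdc, the histamine-producing enzyme of mast cells and basophils, fell by 2.47 (SE 0.45, adjusted p = 0.0146), and the polycomb chromobox gene Cbx6 fell by 1.30 (SE 0.24, adjusted p = 0.0146). Ncam1, a neural cell adhesion molecule, rose (log2 1.29, SE 0.23, adjusted p = 0.0126). The Ncam1 call rests on BMA3, where the mean signal was 76.2, and without BMA3 its log2 difference was -0.03 (adjusted p = 0.938). Hdc signals were 121 in FLA2, 148 in FLB1 and 68.7 in BMA3 but 2924 in FLB2 and 7891 in BMA5, and the Hdc call ended without BMA5 (adjusted p = 0.431) or FLB2 (0.106). Calls also ended without leukemia BMA5 for Nudt9 (0.0583), Tmppe (0.0777), Lcorl (0.128), Clec11a (0.1), Zmynd11 (0.112) and Cbx6 (0.1), without FLB2 for Lcorl (0.0911), without BMA3 for Cbx6 (0.0969) and Clec11a (log2 0.91, under 2-fold), and without FLB1 for Zmynd11 (log2 0.99). Single arrays ended other calls. Eif2s3y lost its call without FLA2 replicate 3 (0.0514), Tmppe without FLA2 replicates 2 (0.0579) and 3 (0.106), Cbx6 without FLA2 replicate 1 (0.13), Hdc without FLA2 replicates 2 (0.094) and 3 (0.0565), and Ncam1 without FLA2 replicates 1 (0.12) and 2 (0.0645). Clec11a lost its call without any of the FLA2 arrays (up to 0.145) or BMA3 replicate 1 (log2 0.96), and Zmynd11 without any of the FLA2 arrays (up to 0.135), FLB1 replicate 2 (log2 0.98) or FLB2 replicate 2 (log2 0.89). Lcorl lost its call without any of the FLA2 or BMA5 arrays, FLB1 replicate 2, FLB2 replicate 1 or BMA1 replicate 2 (up to 0.164).

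With the mean over all probe sets of a gene, the calls of Zmynd11 (log2 0.45, adjusted p = 0.0891), Tfpi (1.18, 0.0726), Ncam1 (0.83, 0.0891) and Atp6v1a (-0.91, under 2-fold) ended. The other probe sets had log2 differences of 0.13 and 0.17 for Zmynd11, 1.11 and 1.03 for Tfpi, 0.36 for Ncam1, -0.66 for Atp6v1a and -5.62 and -2.51 for Xist. Calls also ended with no filter for Lcorl and Clec11a, without the mean-variance trend for Lcorl, Clec11a and Zmynd11, after median centring for Clec11a and Zmynd11, with only the groups of the contrast for Clec11a, and with BMA1 added to the comparison for Lcorl, Clec11a and Ncam1. Against FLB1 and FLB2 alone they ended for Eif2s3y, Tfpi, Lcorl, Clec11a, Zmynd11, Tmppe, Nudt9, Cbx6, Hdc and Ncam1, and on leukemia means for every named gene.

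In all, 25 of 8529 genes were called, 12 higher and 13 lower, and 1335 genes had an unadjusted p under 0.05 in limma. Without FLB1 replicate 3 the count was 43. Every FL array was scanned in session 1 and every BMA3 and BMA5 array in session 2. Session as a block rests on BMA1, the only leukemia in both sessions, with replicate 1 alone in session 1. Chip lot as a block rests on BMA3, the only leukemia in more than 1 lot, with 1 array in each. With session as a block 11 genes were called, of which 10 were among the 25, and within session 1, where FLB1 and FLB2 are the comparison, 10 genes were called, of which 6 were among the 25. Named genes that lost their call with session as a block were Nudt9 (log2 -1.22, adjusted p = 0.0747), Tmppe (-1.48, 0.212), Cbx6 (-1.25, 0.215), Hdc (-1.77, 0.35), Lcorl (0.87, 0.481), Clec11a (1.13, 0.206), Zmynd11 (1.29, 0.0855) and Ncam1 (1.32, 0.187). These 8 genes were not called within session 1 either, nor were Ddx4 (log2 -2.37, adjusted p = 0.12), Atp6v1a (-1.13, 0.106) and Tfpi. With session as a block the differences of Nudt9, Tmppe, Clec11a, Zmynd11 and Ncam1 were no smaller than without it. Those of Cbx6, Hdc and Lcorl were smaller. A call lost with this block therefore does not by itself show an effect of the session. Chip lot as a block ended the calls of Lcorl, Zmynd11, Tmppe, Cbx6 and Hdc, and fluidics station as a block those of Clec11a, Zmynd11, Cbx6 and Ncam1. Within lot 1 the calls of Lcorl, Zmynd11, Tmppe, Nudt9, Cbx6 and Hdc ended. Within station 1, where BMA3 is the only comparison leukemia, those of Lcorl, Clec11a, Zmynd11, Ddx4, Jchain, Tmppe, Atp6v1a, Nudt9 and Hdc ended. Station 2 holds only replicate 3 of FLA2, so calls within it are not given. The count was 26 with chip lot as a block, 15 of them among the 25, and 25 with fluidics station as a block, 18 of them shared. Within lot 1 it was 22 (14 shared), and within station 1 it was 29 (11 shared). The Igha difference was -3.23 with session as a block (adjusted p = 0.00185), -3.05 with chip lot and -2.71 within session 1 (0.00464). The Igha values were -3.05 within lot 1, -3.46 within station 1 and -2.62 within station 2. For Jchain the difference was -2.97 with session as a block (0.00185) and -2.42 within session 1 (8.81e-05). Within station 1 it was -2.59 (0.0506), and within station 2 it was -2.27. The Igkv8-30 difference was -2.20 within session 1 (0.00182), and the Tfpi difference was 0.92 there (0.16). The median log2 change of all genes was 0.06, against 0.01 after quantile normalization and -0.12 after median centring of each array.

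Of the gene lists, ribosomal protein genes were higher in FLA2, with 33 of 38 positive and a median log2 difference of 0.29 (camera adjusted p = 1.04e-07). With an estimated correlation the adjusted p = 0.53. The median was 0.14 after quantile normalization, 0.11 after median centring, 0.20 with session as a block (0.00513) and 0.26 within session 1 (6.03e-06). Late granule genes of neutrophils, such as Ngp (log2 0.34) and Chil3 (log2 0.76), had a median of 0.43 with 15 of 16 positive (camera adjusted p = 3.71e-04; adjusted p = 0.579 with an estimated correlation). Their median was 0.25 after median centring, 0.27 with session as a block (0.373) and 0.06 within session 1 (0.826). Megakaryocyte and platelet genes, such as Pf4 (log2 0.69), had a median of 0.44 with 12 of 13 positive (camera adjusted p = 0.035; adjusted p = 0.731 with an estimated correlation). FLA2 replicate 3 stands apart, with a mean of 9.61 over these genes against 10.47 and 10.54 in replicates 1 and 2, and lies under FLB1 replicates 2 (9.65) and 3 (10.36), FLB2 replicate 2 (9.72), BMA3 replicate 2 (10.34) and every BMA5 array (9.81 to 9.87). The list median was 0.26 after median centring, and its adjusted p was 0.303 with session and 0.193 with fluidics station as a block, and 0.0147 within session 1. Interferon response genes had a median of -0.22 with 16 of 25 negative (camera adjusted p = 0.035; adjusted p = 0.817 with an estimated correlation), and their median was 0.10 with session as a block (0.832), -0.47 within session 1 (1.96e-06) and -0.40 after median centring (0.131). Oxidative phosphorylation genes, such as Cox6b1 (log2 0.36), had a median of 0.12 with 60 of 73 positive (camera adjusted p = 0.035; adjusted p = 0.711 with an estimated correlation), and -0.06 after median centring (0.495). Their adjusted p was 0.832 with session and 0.12 with chip lot as a block, and 0.237 within session 1. No member of these 5 lists was called over all genes, and adjusted over the list alone 1 interferon gene, Ifi27l2a, was lower (log2 -1.66). The ratio of 3' to 5' Gapdh signal, a sign of RNA quality, was 5.65 ± 2.03 (SD, n = 3) in FLA2 and 10.5 ± 2.95 (n = 10) in the low-frequency leukemias (2-sided exact permutation p = 0.014 over 286 permutations, adjusted p = 0.0559 over 4 tests). For actin the ratio was 6.81 against 8.31 (exact permutation p = 0.178, adjusted p = 0.19). Both tests treat arrays of a leukemia as separate units, while FLA2 is a single leukemia.

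The interferon call ended without FLA2 replicates 1 (0.192) and 3 (0.0675), FLB1 replicate 3 (0.151), FLB2 replicate 1 (0.0565) or BMA3 replicates 1 (0.0566) and 2 (0.0552). The megakaryocyte call ended without FLA2 replicates 1 (0.242) and 2 (0.241), FLB1 replicate 2 (0.0688), FLB2 replicate 1 (0.087) or BMA3 replicates 1 (0.0566) and 3 (0.068). The oxidative phosphorylation call ended without FLA2 replicates 1 (0.302) and 2 (0.0604), FLB1 replicate 3 (0.0715), FLB2 replicates 1 (0.0565) and 2 (0.0519), BMA3 replicates 1 (0.0566) and 2 (0.0552) or BMA5 replicate 3 (0.0712). The number of lists called, 5, was 2 without FLA2 replicate 1, FLB2 replicate 1 or BMA3 replicate 1 and 3 without FLB1 replicate 3.

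The other lists did not pass the camera test. Adjusted p-values were 0.48 for Hox genes and cofactors, 0.0667 for HSC and progenitor genes, 0.412 for polycomb genes, 0.412 for cell cycle genes, 0.954 for cell cycle inhibitors, 0.224 for primary granule genes and 0.48 for monocyte and macrophage genes. They were 0.733 for MHC class II genes, 0.859 for B-cell genes, 0.412 for T- and NK-cell genes, 0.412 for erythroid genes, 0.725 for mast-cell, basophil and eosinophil genes and 0.412 for marrow stroma and endothelium genes. They were 0.113 for both Wnt and Notch genes, 0.71 for adhesion and homing genes, 0.65 for immediate early and stress genes, 0.819 for glycolysis genes, 0.859 for hypoxia genes, 0.923 for sex-linked genes and 0.0667 for proteasome genes. Over all genes Cbx6 was the called polycomb gene, Jchain the called B-cell gene, Hdc the called mast-cell gene and Ncam1 the called adhesion gene. Adjusted over the list alone, the HSC transcription factor gene Mecom was lower (log2 -1.35), the stroma gene Mgp was higher (log2 1.15), and among sex-linked genes Eif2s3y and the Y-linked Kdm5d (log2 1.29) were higher and Xist was lower. These genes and the others named as passing over a list alone but not over all genes were picked out after their values were seen. The median, mean and test differed in sign for B-cell genes (median 0.25, mean -0.04, test up), mast-cell genes (median 0.26, mean -0.08, test down), adhesion genes (median -0.07, mean 0.04, test down), stress genes (median 0.01, mean -0.06, test down), cell cycle genes (median -0.01, mean 0.01, test down), MHC class II genes (median -0.01, mean 0.01, test down) and sex-linked genes (median 1.29, mean 0.82, test down).

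**Figure D2:**
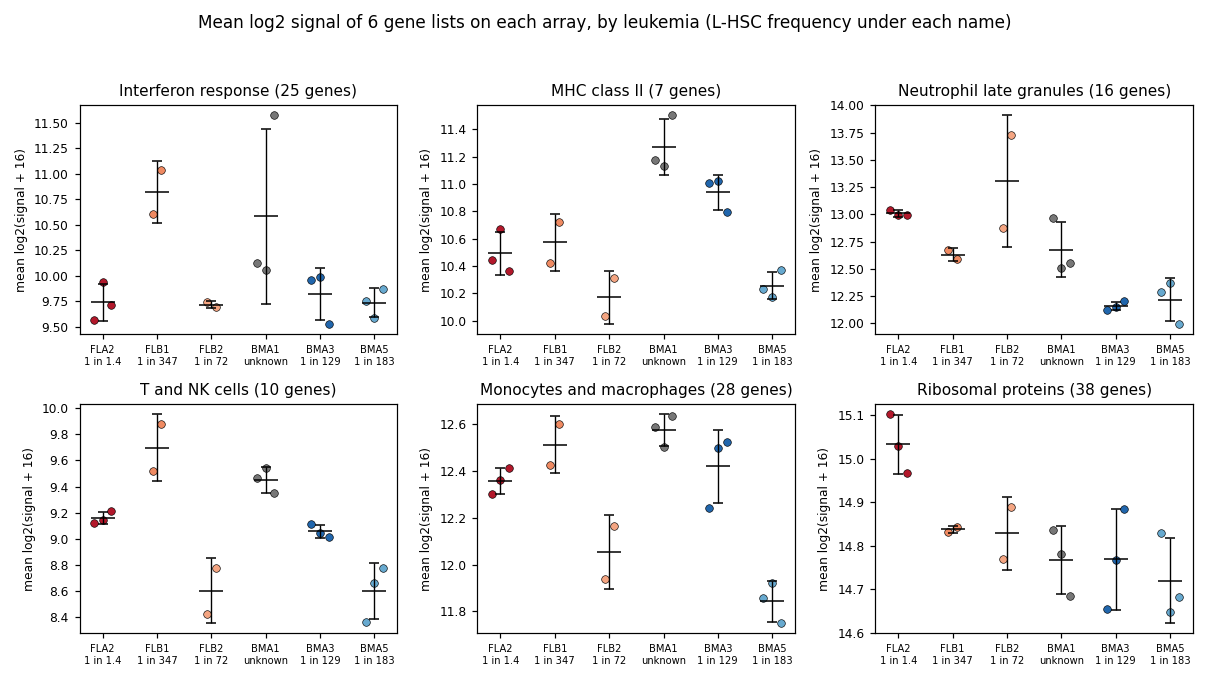
Mean log2(signal + 16) over the measured genes of 6 lists, with a point per array and a bar with whiskers for the mean and SD in each leukemia. Interferon response genes average 10.82 in FLB1 and 10.58 in BMA1 but 9.72 to 9.83 in the other leukemias, and late granule genes average 13.31 in FLB2 and 12.16 in BMA3.

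FLA2 and FLB1, both from fetal liver cells, have the highest and the lowest labelled L-HSC frequency. Fundc2, a protein of the mitochondrial outer membrane, was 13.5-fold higher in FLA2 (log2 3.76, SE 0.18, adjusted p = 8.64e-10), with signals of 6658 ± 151 (SD, n = 3) in FLA2 and 480.1 ± 78.1 (n = 2) in FLB1. Pttg1, the securin that holds sister chromatids together until anaphase, was higher by 3.57 (SE 0.19, adjusted p = 3.21e-09), with signals of 34641 ± 8704 and 2853 ± 348. The other leukemias had signals near those of FLA2, between 7043 and 7874 for Fundc2 and between 21572 and 27410 for Pttg1. The size of both differences depends on the probe set. The other Fundc2 probe set had 2.07, those of Pttg1 had 1.73 and 1.47, and the means over all probe sets were 2.91 and 2.26, both called. Ifi27l2a, an interferon-induced gene, fell by 3.57 (SE 0.58, adjusted p = 0.00809), from 3853 ± 152 in FLB1 to 382 ± 315 in FLA2, and Ifi47, an interferon-induced GTPase, fell by 1.67 (SE 0.30, adjusted p = 0.0181).

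Dmrtb1, a transcription factor of the germ line, fell by 3.57 (SE 0.30, adjusted p = 2.13e-06), from 4746 ± 883 in FLB1 to 399 in FLA2. Rises were also found at Mgp, an inhibitor of calcification (log2 2.82, SE 0.41, adjusted p = 0.00263), Lrg1, a secreted glycoprotein (log2 2.60, SE 0.44, adjusted p = 0.0106), and H2-M10.1 (log2 2.56, SE 0.47, adjusted p = 0.0229). Igha fell by 2.25 (SE 0.41, adjusted p = 0.0229), Jchain fell by 2.12 (SE 0.41, adjusted p = 0.0348) and Igkv8-30 fell by 2.09 (SE 0.33, adjusted p = 0.00647). At the sex-linked genes, Eif2s3y rose by 7.37 (SE 1.01, adjusted p = 0.00149; 5.79 with pseudocount 64 and 8.99 with pseudocount 1) and Xist fell by 5.34 (SE 0.30, adjusted p = 4.86e-09). The log2 difference of Hoxa9 was 0.42 (SE 0.21, adjusted p = 0.755). Several calls ended without a single array. These were Eif2s3y without FLA2 replicate 3 (0.06), Mgp without FLB1 replicate 3 (0.0582), Lrg1 without FLA2 replicates 1 (0.059) and 2 (0.0551), Ifi27l2a without FLB1 replicate 3 (0.0626), Ifi47 without FLA2 replicates 1 (0.078) and 3 (0.0716) and FLB1 replicate 3 (0.178), and Igkv8-30 without FLB1 replicate 3 (0.0841). H2-M10.1 and Igha ended without any of the FLA2 arrays or FLB1 replicate 2 (up to 0.109 and 0.172), and the Igha difference was -1.44 without FLB1 replicate 2. Jchain ended without any of the FLA2, FLB1 or BMA5 arrays or FLB2 replicate 1 (up to 0.199).

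In all, 18 genes were called, 10 higher and 8 lower, and 598 had an unadjusted p under 0.05. Without FLB1 replicate 2, which leaves FLB1 with a lone array that is assumed to vary like the other groups, 76 genes were called, 64 higher and 12 lower, of which 12 were among the 18. All arrays of both leukemias share session 1 and chip lot 1, and within them 12 and 15 genes were called. With fluidics station as a block 11 genes were called, 5 higher and 6 lower. Station 1 holds no FLB1 array and station 2 holds only replicate 3 of FLA2, so calls within a station are not given. With station as a block the difference was -1.96 for Igha (adjusted p = 0.247), -1.70 for Jchain (0.376), -2.07 for Igkv8-30 (0.0609), -1.82 for Ifi47 (0.0609), 2.02 for Lrg1 (0.161) and 2.71 for H2-M10.1 (0.103), so these 6 calls ended. It was 3.82 for Fundc2 and 3.35 for Pttg1. Within session 1 the calls of Mgp (0.0882), Lrg1 (0.0931), H2-M10.1 (0.145) and Igha (0.081) ended. Within lot 1 the calls of Lrg1 (0.0635) and H2-M10.1 (0.0973) ended, and with only the groups of the contrast those of Mgp, Lrg1, H2-M10.1, Igha and Igkv8-30. Calls also ended with the mean over all probe sets for Igha (0.0509), without the mean-variance trend for Igha, Jchain and Ifi47, with no filter for Jchain, with the stricter filter for Eif2s3y, with the replicate block for H2-M10.1, and with array weights for H2-M10.1 and Jchain.

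Interferon response genes had a median log2 difference of -0.90, with 23 of 25 negative, 2 called lower and 6 lower when adjusted over the list alone, among them Ifi35 (log2 -2.39) and Rsad2 (log2 -2.05) (camera adjusted p = 8.75e-14; adjusted p = 0.25 with an estimated correlation), and the median was -1.25 with station as a block. Primary granule genes of neutrophils had a median of 0.34 with 10 of 12 positive, and Elane, the neutrophil elastase, was higher when adjusted over the list alone (camera adjusted p = 1.95e-04; adjusted p = 0.25 with an estimated correlation). Late granule genes had a median of 0.44 with 12 of 16 positive (camera adjusted p = 0.00194; adjusted p = 0.563 with an estimated correlation), and ribosomal protein genes 0.21 with 33 of 38 positive (camera adjusted p = 1.57e-05; adjusted p = 0.409 with an estimated correlation). Monocyte and macrophage genes had a median of -0.12 with 19 of 28 negative (camera adjusted p = 0.0342; adjusted p = 0.556 with an estimated correlation). T- and NK-cell genes had a median of -0.42 with 8 of 10 negative, and Gzma, a protease of cytotoxic lymphocytes, was lower when adjusted over the list alone (camera adjusted p = 0.0432; adjusted p = 0.25 with an estimated correlation). Hypoxia genes had a median of 0.13 with 14 of 17 positive (camera adjusted p = 0.0432; adjusted p = 0.563 with an estimated correlation). No granule, ribosomal, monocyte, T- and NK-cell or hypoxia gene was called over all genes. Without FLB1 replicate 3, 4 lists were called instead of 7, and the calls of primary granule (0.126), monocyte (0.44), T- and NK-cell (0.558) and hypoxia genes (0.978) ended. Without FLB1 replicate 3 the medians were 0.20 for primary granule, -0.21 for T- and NK-cell and -0.02 for hypoxia genes, and without FLB1 replicate 2 they were 0.52 for primary granule, 0.12 for ribosomal protein, -0.28 for monocyte and 0.51 for hypoxia genes. The monocyte call also ended without FLA2 replicate 2 (0.0642). The T- and NK-cell call ended without FLA2 replicates 1 (0.0841) and 3 (0.0631) or BMA3 replicate 3 (0.0503), and the hypoxia call without FLA2 replicates 1 (0.12) and 3 (0.122), BMA1 replicate 3 (0.0503) or BMA5 replicates 2 (0.0514) and 3 (0.0502). With station as a block the monocyte (0.169) and the T- and NK-cell calls (0.0627) ended, and after median centring the hypoxia call (0.0608). The replicate block ended the monocyte (0.0561), T- and NK-cell (0.0769) and hypoxia (0.0998) calls. The ratio of 3' to 5' Gapdh signal was 5.65 ± 2.03 (SD, n = 3) in FLA2 and 11.7 ± 6.00 (n = 2) in FLB1. FLB1 replicate 2 had 15.97 and replicate 3 had 7.48, against 3.73 to 7.77 in the FLA2 arrays. This difference of RNA quality was not tested. Without FLB1 replicate 2 the primary granule, monocyte and hypoxia medians were larger in size and the ribosomal protein median was smaller. Not all of these lists therefore go along with the ratio.

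BMA1, of unknown frequency, was set against BMA3 and BMA5, the other leukemias from bone marrow cells. H2-Aa, a chain of MHC class II, rose 4.68-fold (log2 2.23, SE 0.31, adjusted p = 0.00305), with signals of 11509.6 ± 2379.7 (SD, n = 3) in BMA1, 5547 ± 2739 (n = 3) in BMA3 and 1172 ± 112 (n = 3) in BMA5, and H2-Eb1, another class II chain, rose by 1.16 (SE 0.23, adjusted p = 0.0206). Klrd1, a receptor of NK cells, rose by 1.82 (SE 0.37, adjusted p = 0.0219), and Vcam1, an adhesion molecule of stroma and macrophages, by 1.18 (SE 0.22, adjusted p = 0.0154). Mt2, a metal-binding metallothionein, fell by 1.45 (SE 0.17, adjusted p = 0.000503), and H1f2, a linker histone, fell by 1.44 (SE 0.17, adjusted p = 0.000503).

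Lpl, which releases fatty acids from lipoproteins, rose by 1.49 (SE 0.24, adjusted p = 0.00703). Upb1, an enzyme of pyrimidine breakdown, rose by 2.45 (SE 0.52, adjusted p = 0.0271), Cox6a2, a cytochrome c oxidase subunit, by 1.48 (SE 0.26, adjusted p = 0.0106), and Trim34a, an interferon-induced gene, by 1.36 (SE 0.24, adjusted p = 0.0125). Lat, an adaptor of T-cell receptor signaling, fell by 1.78 (SE 0.33, adjusted p = 0.0154), Vat1 fell by 1.66 (SE 0.33, adjusted p = 0.0206), Cirbp, a cold-inducible RNA-binding protein, fell by 1.29 (SE 0.30, adjusted p = 0.0496) and Afg3l1, a mitochondrial protease, fell by 1.28 (SE 0.26, adjusted p = 0.0207). Among list members Ncam1 rose by 3.03 (adjusted p = 4.25e-06), with a signal of 4681 in BMA1, 76.2 in BMA3 and 3979 in BMA5. Mgst1, a glutathione transferase, rose by 1.01 (adjusted p = 0.00703), with signals of 4785 in BMA1, 1053 in BMA3 and 5266 in BMA5, and Ifi47 rose by 1.00 (adjusted p = 0.0428). Sox4, a transcription factor of progenitors, fell by 1.27 (adjusted p = 0.0219), and Dusp6, a phosphatase of ERK, fell by 1.37 (adjusted p = 0.0106). The log2 difference of Hoxa9 was -0.24 (SE 0.16, adjusted p = 0.52).

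No single array ended the calls of H2-Aa, Lpl, Mt2, H1f2 or Ncam1. Those of H2-Aa, Lpl, Mt2 and H1f2 ended within station 1, where BMA3 is the only comparison leukemia, and that of Lpl also within session 2. The Ncam1 difference was 0.21 within station 2, which holds no BMA3 array. Upb1, Klrd1 and H2-Eb1 lost theirs without any of the BMA1 arrays (up to 0.181, 0.181 and 0.16). Calls ended without BMA1 replicate 3 for Cox6a2 (0.1) and Trim34a (0.077), without BMA1 replicates 1 (0.0954) and 3 (0.0936) for Lat, without BMA1 replicates 2 and 3 for Afg3l1 (up to 0.168), Vcam1 (0.102) and Dusp6 (0.0833), and without BMA1 replicates 2 and 3 or BMA5 replicates 1 and 3 for Vat1 (0.14). Sox4 lost its call without BMA1 replicates 1 (0.158) and 3 (0.077) or BMA5 replicate 3 (0.0527). Mgst1 fell under 2-fold without BMA1 replicates 1 and 2, BMA3 replicates 1 and 2 or BMA5 replicates 1 and 3 (lowest log2 0.85). Cirbp lost its call without any of the FLA2, FLB2 or BMA5 arrays, BMA1 replicates 2 and 3 or BMA3 replicate 3 (up to 0.236). Ifi47 lost it without any of the FLA2, FLB2 or BMA1 arrays, BMA3 replicates 1 and 3 or BMA5 replicates 1 and 2 (up to 0.25). With the mean over all probe sets the calls of H1f2 (log2 -0.99, under 2-fold), Vat1 (0.107), Cirbp (0.0563) and Sox4 (0.0652) ended. The other probe sets had -1.36 and -0.17 for H1f2, -0.36 to -1.02 for Sox4, 0.68 and 2.02 for Vcam1 and 1.30 for Ncam1. Median centring ended the calls of Mgst1, Vcam1, H2-Eb1 and Ifi47, and the fit without the trend those of Cirbp, Afg3l1, Sox4, H2-Eb1 and Ifi47. Calls also ended with only the groups of the contrast for Lat, Vcam1, Cirbp and Ifi47, with pseudocount 64 for Mgst1 and Ifi47, with pseudocount 1 and after quantile normalization for Cirbp, with no filter for Cirbp and Ifi47, with the stricter filter for Vat1, and with array weights and the replicate block for Ifi47.

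In all, 41 genes were called, 29 higher and 12 lower, and 1222 had an unadjusted p under 0.05. Without BMA1 replicates 1, 2 and 3 in turn, 24, 26 and 12 genes were called. With session as a block 24 genes were called, of which 17 were among the 41. BMA1 is the only leukemia in both sessions, so this block gives the same differences as leaving out BMA1 replicate 1. BMA3, with 1 array in each lot, is the only leukemia in more than 1 lot. Chip lot as a block therefore sets BMA1 against BMA3 replicate 1 and ties BMA5 to it through BMA3 replicate 2. Calls lost with the lot block do not by themselves show an effect of the lot. With chip lot as a block 27 were called, 26 higher and 1 lower, of which 10 were among the 41, and with fluidics station as a block 36. Within session 2 the count was 6. Within station 1, where BMA3 is the only comparison leukemia, it was 6. Within lot 1 BMA3 replicate 1 is the only comparison array, and within station 2 BMA1 replicate 1 alone is set against BMA5. For both, only differences are given here. The H2-Aa difference was 2.39 with session as a block (adjusted p = 0.00904) and within session 2 (0.0291). It was 2.08 with chip lot (0.0524), 2.13 with station, 0.75 within lot 1, 1.35 within station 1 (0.544) and 2.94 within station 2. Mt2 differed by -1.54 with session as a block (0.00261), -1.18 with chip lot (0.144), -0.38 within lot 1 and -0.76 within station 1 (0.544). For H1f2 the difference was -1.73 with chip lot (0.0369), -0.85 within lot 1 and -0.68 within station 1 (0.544). Mean signals in BMA1, BMA3 and BMA5 were 1615, 2607 and 7646 for Mt2 and 5436, 8669 and 26089 for H1f2, so both differences are smaller against BMA3 than against BMA5. The Lpl difference was 2.08 with chip lot (0.0146), 1.22 within lot 1 and 1.48 within session 2 (0.0959). The Ncam1 difference was 3.05 with session as a block and 3.82 with chip lot. It was 6.16 within lot 1, 5.84 within station 1 and 0.21 within station 2, which holds no BMA3 array. With session as a block the calls of Upb1 (adjusted p = 0.117), Klrd1 (0.0528), Lat (0.114), Sox4 (0.156), H2-Eb1 (0.0716), Ifi47 (0.0949) and Mgst1 (log2 0.85, under 2-fold) ended. With chip lot as a block those of Upb1 (0.433), Klrd1 (0.472), Cox6a2 (0.387), Trim34a (log2 0.71, adjusted p = 0.595), Lat (0.497), Vat1 (0.546), Cirbp (0.442), Afg3l1 (0.442), Sox4 (0.14), Mgst1 (0.0879), H2-Eb1 (0.415), Ifi47 (0.28) and Dusp6 (0.415) ended, and with station as a block those of Cirbp (0.0572) and Ifi47 (0.0688). Of the named genes only Lpl, H1f2, Vcam1 and Ncam1 were called with chip lot as a block. Within session 2 only H2-Aa, Klrd1, Mt2, H1f2, Afg3l1 and Ncam1 were, and within station 1 only Mgst1, Ncam1 and Dusp6. The median log2 change of all genes was 0.09, against 0.02 after quantile normalization and -0.10 after median centring.

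MHC class II genes had a median log2 difference of 0.44 with 6 of 7 positive, and 2 were called over all genes and 2 when adjusted over the list alone (camera adjusted p = 0.00125; adjusted p = 0.0544 with an estimated correlation). Monocyte and macrophage genes had a median of 0.41 with 23 of 28 positive, and Vcam1 was called over all genes and Vcam1 and Cx3cr1, a chemokine receptor, when adjusted over the list alone (camera adjusted p = 6.47e-06; adjusted p = 0.0544 with an estimated correlation). T- and NK-cell genes had a median of 0.46 with 10 of 10 positive and 1 called (Klrd1; camera adjusted p = 0.00509; adjusted p = 0.0544 with an estimated correlation), and this call ended with chip lot as a block (0.0874). Interferon response genes had a median of 0.78 with 23 of 25 positive, 1 called and 6 when adjusted over the list alone, among them Ifit3 (log2 1.68) and Ifi35 (log2 1.57) (camera adjusted p = 7.83e-07; adjusted p = 0.359 with an estimated correlation). Without BMA1 replicate 3, whose interferon genes averaged 11.57, the interferon median was 0.22 (0.11). Late granule genes had a median of 0.48 with 14 of 16 positive, and Chil3 was higher when adjusted over the list alone (log2 1.04; camera adjusted p = 2.73e-05; adjusted p = 0.251 with an estimated correlation). Marrow stroma and endothelium genes had a median of 0.55 with 14 of 16 positive, and Vcam1 was called (camera adjusted p = 0.0058; adjusted p = 0.393 with an estimated correlation). After median centring the medians were 0.25 for MHC class II, 0.22 for monocyte, 0.27 for T- and NK-cell, 0.29 for late granule and 0.37 for stroma genes, and after quantile normalization that of T- and NK-cell genes was 0.25. With chip lot as a block the medians were 0.26 for MHC class II and 0.92 for stroma genes. Monocyte genes averaged 12.57 in BMA1, 12.42 in BMA3 and 11.84 in BMA5, so their rise was mainly against BMA5.

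Proteasome genes had a median of -0.16 with 33 of 38 negative (camera adjusted p = 4.96e-07; adjusted p = 0.0544 with an estimated correlation), and the difference of Psma6 was -0.68 (adjusted p = 0.0154, under 2-fold). Oxidative phosphorylation genes had a median of -0.14 with 58 of 73 negative (camera adjusted p = 2.32e-06; adjusted p = 0.0544 with an estimated correlation), although the called member, Cox6a2, rose. Glycolysis genes had a median of -0.25 with 14 of 19 negative (camera adjusted p = 1.01e-04; adjusted p = 0.0544 with an estimated correlation). Hypoxia genes had a median of -0.20 with 11 of 17 negative (camera adjusted p = 0.00795; adjusted p = 0.387 with an estimated correlation), and their call ended after quantile normalization (0.0617) and with chip lot as a block (0.0851). No proteasome, glycolysis or hypoxia gene was called. Oxidative phosphorylation genes averaged 12.87 in BMA1, 12.88 in BMA3 and 13.06 in BMA5, so their fall was mainly against BMA5. After median centring the medians were -0.35 for proteasome, -0.33 for oxidative phosphorylation, -0.44 for glycolysis and -0.39 for hypoxia genes. The oxidative phosphorylation median was -0.08 after quantile normalization and -0.06 without BMA1 replicate 3, the proteasome median -0.30 with chip lot as a block, and the hypoxia median -0.06 without BMA1 replicate 2 and -0.02 without BMA3 replicate 3. The 3' to 5' ratio of Gapdh was 14.2 ± 5.10 (SD, n = 3) in BMA1 and 10.02 ± 2.22 (n = 6) in BMA3 and BMA5 (2-sided exact permutation p = 0.0952 over 84 permutations, adjusted p = 0.19), and that of actin was 9.03 against 7.30 (exact permutation p = 0.19).

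On the 25 genes called in FLA2, the median position of BMA1 between the low-frequency mean, 0, and FLA2, 1, was 0.0227, and BMA1 lay nearer to FLA2 at 5 genes, Clec11a, Lpl, Ncam1, Pdlim1 and Pttg1, of which Lpl, Pdlim1 and Pttg1 were picked out after their values were seen. The position was -0.0719 without BMA1 replicate 3. Measured in the same way, each against the other low-frequency leukemias, on the genes called with that leukemia kept in the fit but left out of the contrast, the position was 0.529 for FLB1 (59 genes), 0.493 for FLB2 (38 genes), 0.318 for BMA3 (32 genes) and 0.00303 for BMA5 (23 genes). These positions differ from that of BMA1 in genes and in comparison leukemias, so they are not directly comparable with it. FLB1 and FLB2 also share origin, session 1 and chip lot 1 with FLA2. BMA1 had the highest mean Igha signal, 32467 ± 7235 (SD, n = 3), and the highest mean Jchain signal, 7458 ± 3416 (n = 3).

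The comparison of fetal liver with bone marrow origin asks what the cell of origin leaves in the leukemia. Stfa3, a stefin A inhibitor of cysteine proteases, was higher in the FL leukemias by 4.30 on the log2 scale (SE 0.42, adjusted p = 0.0126, n = 3 against 3 leukemia means; 3.62 with pseudocount 64 and 4.66 with pseudocount 1). Its mean signals were 2698 ± 441 (SD, n = 3) in FLA2, 823 ± 215 (n = 2) in FLB1 and 1877 ± 1247 (n = 2) in FLB2, against 61.8, 67.6 and 95.7 in BMA1, BMA3 and BMA5, which are far under the array medians, so the size of the difference depends on the pseudocount. It was the only gene called by limma, and 664 genes had an unadjusted p under 0.05. The call ended without leukemia FLA2 (adjusted p = 0.371), FLB2 (0.155) or BMA1 (0.0737), with the stricter filter (0.388) and without the mean-variance trend (0.0572), and the count was 3 without FLB1 and 2 without BMA3. The Stfa3 difference was 5.33 with session as a block, 4.65 with chip lot, 4.50 with fluidics station and 5.27 within session 1, where BMA1 replicate 1 is the only BM array. With session as a block 186 genes were called, 121 higher and 65 lower, a count that rests on BMA1, the only leukemia in both sessions. The blocked fit takes the adjusted leukemia means as free of error. Its p-values and the count of 186 leave out the error of the session term, so no conclusion is drawn from that count. The log2 difference of Hoxa9 was -0.41 (SE 0.19, adjusted p = 0.654).

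Late granule genes were higher in the FL leukemias, with a median log2 difference of 0.69 and 15 of 16 positive, and Camp, S100a8 and Fpr2 were higher when adjusted over the list alone (camera adjusted p = 3.89e-07; adjusted p = 0.578 with an estimated correlation). Examples are Ngp (log2 0.52) and Chil3 (log2 0.86), neither called. With session as a block the median was 0.27 (0.262). The late granule list averaged 13.01 in FLA2, 12.63 in FLB1 and 13.31 in FLB2, against 12.68 in BMA1, 12.16 in BMA3 and 12.22 in BMA5. FLB1 thus lay below BMA1. Oxidative phosphorylation genes had a median of 0.14 with 62 of 73 positive (camera adjusted p = 4.95e-05), 0.05 after median centring and 0.02 with session as a block (0.661). Ribosomal protein genes had a median of 0.18 with 30 of 38 positive (camera adjusted p = 7.2e-05), 0.03 after quantile normalization (0.39), 0.09 after median centring and an adjusted p of 0.823 with session as a block. Cell cycle genes had a median of 0.13 with 24 of 38 positive (camera adjusted p = 0.0463), and medians of 0.04 both after median centring (0.106) and with chip lot as a block (0.654). MHC class II genes had a median of -0.26 with 7 of 7 negative (camera adjusted p = 0.00809), and -0.50 with session as a block (0.225). The MHC class II list averaged 10.26 in BMA5, below 10.49 in FLA2 and 10.57 in FLB1. HSC and progenitor genes had a median of -0.13 with 14 of 20 negative (camera adjusted p = 0.0116), against 0.585 with session, 0.0786 with chip lot and 0.085 with station as a block, and medians of -0.21 after quantile normalization and -0.22 after median centring. Marrow stroma and endothelium genes had a median of -0.16 with 12 of 16 negative (camera adjusted p = 0.0116), against 0.224 with session and 0.0962 with station as a block, and a median of 0.08 with chip lot (0.923) and -0.26 after median centring. For each of these 7 lists the adjusted p = 0.578 with an estimated correlation, and no member was called over all genes. Leukemia means also overlapped between origins for oxidative phosphorylation (13.06 in BMA5, 13.04 in FLB2) and stroma genes (10.05 in FLA2, 10.01 in BMA3). They did not overlap for ribosomal protein, cell cycle or HSC and progenitor genes.

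The search for genes that set a single leukemia apart from each of the others found 29 genes, 4 higher and 25 lower. BMA5 had 14. Nfe2l2, a transcription factor of the antioxidant response, was lower in BMA5 (smallest difference from another leukemia -1.87), with a signal of 857 ± 381 (SD, n = 3) against 3015 to 4272 elsewhere, and Cebpg and Rgs2 were lower (smallest differences -1.46 and -1.31). Fut8, a fucosyltransferase, and H1f2 were higher in BMA5 (smallest differences 1.56 and 1.44). BMA3 had 6, all lower, among them Ncam1 (-4.38), Mogat2 (-2.54) and Erdr1 (-2.18). The BMA3 signals of Ncam1 (76.2) and Mogat2 (126.8) are far under the array medians, so the size of these 2 differences depends on the pseudocount. FLB1 had 5, with Dmrtb1 (2.51) and Grb10 (1.84), a growth factor receptor adaptor, higher and Fundc2 (-3.76), Pttg1 (-2.90) and Iftap (-1.32) lower. FLA2 had 3, Igha (-2.25), Jchain (-2.12) and Igkv8-30 (-1.65), all lower. FLB2 had 1, Tmem267 (-2.52), with a signal of 57.2 against 333 to 717 elsewhere, and BMA1 had 0 by limma.

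Without FLB1 replicate 2 the total was 48 and the FLB1 count 26, and without FLB1 replicate 3 the FLB1 count was 10. The FLA2 count was 1 without FLA2 replicates 1 or 3 or FLB1 replicate 3. The FLB2 count was 2 without FLA2 replicate 1 or BMA3 replicate 3, 0 without FLB1 replicate 3 or BMA1 replicate 2, 4 without FLB2 replicate 1 and 7 without FLB2 replicate 2. The BMA1 count was 2 without BMA1 replicate 1. The BMA5 count was 9 without FLB1 replicate 3, 6 and 8 without FLB2 replicates 1 and 2, 24 without BMA3 replicate 3, and 7 and 23 without BMA5 replicates 1 and 3. With session as a block the counts were 3 for FLB1, 3 for BMA3 and 0 for the other leukemias. With chip lot they were 4 for FLB1, 5 for BMA3 and 0 for the others. The session block rests on BMA1 and the lot block on single BMA3 arrays, so no conclusion is drawn from these counts. With fluidics station they were 1 for FLA2, 5 for FLB1, 4 for BMA3 and 14 for BMA5.

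**Figure D3:**
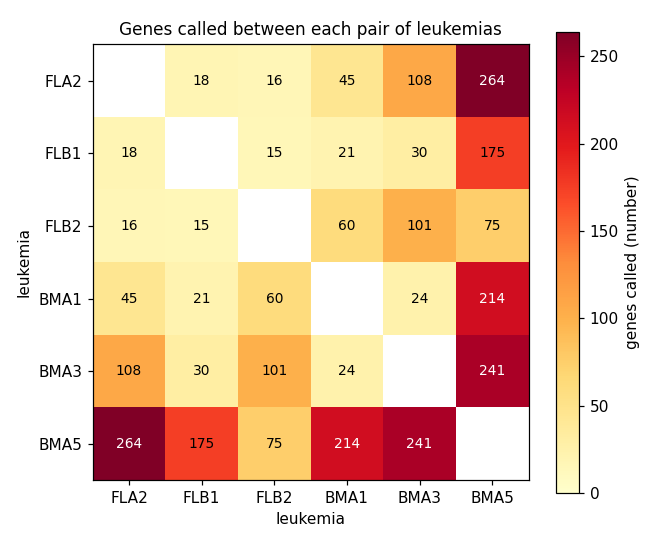
Number of genes called between each pair of leukemias at an adjusted p under 0.05 and 2-fold. FLA2 differs from FLB1 at 18 genes and from FLB2 at 16, while BMA5 differs from the others at 75 to 264.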

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

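Of the tests here, the values of Kdm5d, of Eif2s3y in FLB2 against FLB1 and of the antibody-secreting genes, the values within a session, and the limit of 1 log2 unit above the array median, were chosen only after the result was seen. Dixon's test of the gap of the highest or lowest leukemia over 27 sets of 6 leukemia values singled out 0, and no other kind of unusual result was found.

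The immunoglobulin genes Igha, Jchain and Igkv8-30 were lower in FLA2. The session as the whole source is argued against by the Igha difference of -2.71 within session 1. The difference of -3.23 with session as a block rests on BMA1, the only leukemia in both sessions. Fewer non-leukemic cells of all kinds, fewer B-lineage cells or fewer antibody-secreting cells may each be a source, although the medians of their marker genes, 0.536 (SE 0.263, 5 erythroid genes), 0.245 (SE 0.16, 8 genes) and 0.215 (SE 0.103, 10 genes), went the other way. Only Alas2 (-0.11, SE 0.34), Cd79b (0.19), Cd22 (0.30), Txndc5 (-0.30) and Xbp1 (0.17) lay over 1 log2 unit above the array median, and the bounds set beforehand for the erythroid and B-lineage genes were wrong to count lower signals, which can be unspecific: a probe set of the Y-linked Kdm5d had 203 to 773 in the leukemias where Eif2s3y was at most 95.1. The L-HSC frequency is untested as a source, since FLA2 is its only leukemia.

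Stfa3 was higher in the fetal liver leukemias. If the scanning session were the source, the BMA1 array of session 1 would be higher than the other BMA1 arrays, yet it was lower by a log2 difference of -1.15, a share of -0.268 of the difference between origins. A single array excludes nothing, so session and origin cannot be told apart for Stfa3 from that value. The difference of 5.33 with session as a block rests on the same array, since only BMA1 spans both sessions. Signal shared with related stefin A genes might be a source, and the other stefin A probe set, for Cstdc4 and Csta2, had a difference of 2.56 at a mean signal of 121, but 0 stefin A probe sets besides that of Stfa3 passed the filter, which leaves it open. The origin of the cells is the biological explanation of the design and stays untested beyond 6 leukemias.

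The changes of largest size in FLA2 were at Eif2s3y and Xist. The L-HSC frequency as their source is argued against by Eif2s3y in FLB2, of low frequency, which exceeded FLB1 by 6.82 (SE 0.69). A different sex of the animals is a candidate explanation, and Kdm5d, another Y-linked gene, was higher in FLA2 than in FLB1, BMA1, BMA3 and BMA5 by 1.61 (SE 0.37), past the bound of 1 set for it. Its 2 probe sets that did not pass the filter had -0.77 and 0.57, and those of Uty, also Y-linked and not past it, had 1.19 and 1.41. The labels do not give the sex, and without the sex-linked genes 23 genes were called in FLA2 against the low-frequency leukemias.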

How the results depend on the processing

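Array weights, fits without sex-linked genes, fits within a session, lot or station, and the lists with blocks, with median centring or without each array were chosen after seeing the data, and the others were planned. Counts of called genes stayed within 1.5 times under both pseudocounts, no filter, the mean over all probe sets, array weights and the fit of only the groups of a contrast, for each comparison in which these were run. The count for FLB2 alone moved from 1 to 2 with pseudocount 1 and with array weights and to 3 with the mean over probe sets. The replicate number as a block gave 24, 16, 41, 28 and 1 genes for FLA2 against the low-frequency leukemias, FLA2 against FLB1, BMA1, the leukemia-specific genes and origin. Residuals of arrays with the same number had a median correlation of 0.00698 across 35 pairs (-0.102 to 0.14), so the numbers do not pair the arrays. Low signals near the floor limit what these arrays can show.

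For FLA2 against the low-frequency leukemias, 25 genes became 40 after quantile normalization (25 shared) and 57 after median centring (21 shared). The count was 46 with no fold threshold and 11 with session as a block. It was 14 against FLB1 and FLB2 alone, 10 within session 1 and 0 on leukemia means, where FLA2 is 1 value. Leaving out an array or a leukemia gave 17 (without leukemia BMA5) to 62 (without FLB1), with 38 without BMA3 and 43 without FLB1 replicate 3. For FLA2 against FLB1, 18 became 11 with fluidics station as a block and 12 to 76 without 1 array. For BMA1, 41 became 87 with no fold threshold, 24 with session and 27 with chip lot as a block, 6 within session 2, 16 within lot 1, 6 within station 1, 110 within station 2, and 12 to 53 without 1 array. Within lot 1 BMA3 replicate 1 is the only comparison array, and within station 2 BMA1 replicate 1 is the only BMA1 array. The BMA1 counts of 16 and 110 each rest on a group of 1 array, whose spread cannot be measured. No conclusion is drawn from them, nor from the BMA1 count with chip lot as a block, which rests on single BMA3 arrays. The leukemia-specific total of 29 became 49 with no fold threshold, 6 with session and 9 with chip lot as a block. It was 21 to 48 without 1 array. For origin, 1 became 0 with the stricter filter (Stfa3 adjusted p = 0.388), 0 without the trend (0.0572), 3 with the leukemia as a random block (correlation 0.171), and 0 to 3 without 1 leukemia. The origin count was 186 with session as a block, which leaves out the error of the session term, so no conclusion is drawn from it. The position of BMA1, 0.0227, became -0.276 on genes called at 4-fold, 0.108 after quantile normalization, 0.185 with pseudocount 64, and -0.0719 to 0.0531 without 1 array. The 4-fold alternative uses 10 genes, and apart from that the cause was not tested.

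With an estimated correlation 0 lists were called in each comparison. For FLA2 against the low-frequency leukemias, 5 lists became 1 with fry, 2 with session as a block, 10 with chip lot as a block and 2 to 5 without 1 array. For FLA2 against FLB1, 7 became 0 with fry, 4 with the replicate block and 4 to 8 without 1 array. For origin, 7 became 0 with fry and 3 with session as a block. The cause was not tested.

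Over the named genes and their alternatives, 1587 values kept direction and call, 361 kept direction and lost the call, and 3 reversed. The reversed values were all against the low-frequency leukemias. Ncam1 reversed without leukemia BMA3 (-0.034, the lowest of its leave-outs, which reach 1.96 without FLB2) and within station 2 (-0.40). Hdc reversed within station 1 (0.71). Station 2 holds no array of BMA3, the only leukemia with low Ncam1. Station 1 holds BMA3 as the only low-frequency leukemia, and Hdc was lower in BMA3 than in FLA2. The signs thus follow from which leukemias remain in the fit.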

Other observations

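Of the tests here, the immunoglobulin probe sets and the genes of BMA3 and BMA5 beyond the naming rule were chosen only after the result was seen, as were the counts with each leukemia kept whole, and the splits of the samples were planned.

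Among probe sets for immunoglobulin genes, 17 of 53 passed the filter, 12 of these were negative in FLA2 against the low-frequency leukemias, 7 were called lower and 0 higher by limma, and the median log2 change was -1.19. The other Igha probe sets had differences of -2.38 and -2.55, and the 4 called kappa light chain probe sets had -2.01 to -2.76. Other kappa probe sets, for Igkv9-120 and for Igkv6-14 and related genes, had 0.95 and 0.52, neither called. The 5 probe sets for Ighm, the constant region of IgM, ran from -0.36 to 0.67 and none was called.

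Further genes lower in BMA3 alone were Mgst1 (smallest difference -2.16), Slfn4 (-1.59), of the schlafen family, and Arrdc4 (-1.56). In BMA5 alone, Ampd3 (-1.27), an AMP deaminase, Ifitm6 (-1.25), Hmgn1 (-1.17), a nucleosome-binding protein, Clec4a2 (-1.17), a lectin receptor of myeloid cells, and Thbd (-1.02), the thrombin receptor thrombomodulin, were lower.

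The 25 genes of FLA2 against the low-frequency leukemias were matched by 1 of 100 splits of the same arrays, the real split itself, and the highest other split gave 23. The other splits mix arrays of different leukemias, so this shows only that arrays of a leukemia resemble each other. With each leukemia kept whole, FLB1, FLB2, BMA3 and BMA5 against the 4 others gave 17, 26, 84 and 191, so FLA2 exceeded only FLB1, and 5 leukemias are too few for a share under 0.05. For BMA1, 2 of 84 splits gave at least the real 41, and with each leukemia kept whole BMA3 gave 68 and BMA5 228. The highest other split set the 3 BMA5 arrays against the rest, with the labels of the rest shuffled, and gave 214, and the 3 BMA3 arrays gave 29 in this way. The count of 214 is several times the real one, which points to a structure of the samples. The BMA5 arrays share chip lot 2 and fluidics station 2, and the BMA1 count was 27 with chip lot and 36 with station as a block. The count of 27 rests on single BMA3 arrays, so it does not settle whether the lot matters. For origin, 1 of 10 splits gave as many genes as the real split (1, highest other 0), and 10 splits are too few for a share under 0.05. For the leukemia-specific genes, 1 of 100 regroupings gave as many as the real 29, and the highest other gave 14, but regroupings break up the leukemias, so this count also shows only that arrays of a leukemia resemble each other. For the gene lists of FLA2 against the low-frequency leukemias, 45 of 100 splits gave at least the real 5, with a highest of 10, so chance cannot be excluded for that number of lists.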
